A study of Mus musculus with 18 samples.

How the data were processed

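RNA sequencing of mouse prostate was analysed in 18 libraries, 6 for each of 3 diets. Per the labels, male FVB mice with a prostate-specific deletion of Pten were put on a control diet (AIN93M), a high-fat diet with 60% of its calories from fat, or AIN93M with 0.05% delta-tocotrienol, a form of vitamin E, from 6 weeks of age. Per the labels' protocols, tissue was collected at 20 weeks after a daytime fast of 8 h, and RNA from the dorsal, lateral and ventral glands was enriched for polyadenylated molecules, copied with random hexamers and sequenced on a BGISEQ-500. Each library was treated as 1 mouse. No wild-type library is listed, so the level of Pten could not check the labels. The library labelled control 2 stood apart from the other 17, and it stayed in the fits. Values without it are given beside the results it moved most.

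Per the submitters' processing notes, HISAT, Bowtie2 and RSEM were used with the mouse build mm10, without versions. The authors deposited an expected count per gene and library, estimated by RSEM per the submitters' processing notes, and 87.7% of these values were whole numbers. The authors also deposited FPKM (fragments per kilobase, scaled to library size) for each gene and library, which served here only as an alternative measure. Deposited TPM (transcript abundance) values served only for relative transcript length and were not tested. The file also carried 9 columns of group means, which were not used. It listed 19169 genes by NCBI Gene number. A spreadsheet had turned 25 symbols into dates, and these were resolved through the gene number. A further 10 symbols were bare numbers, and 2 were on duplicated rows. Of the gene numbers, 99.3% matched the reference annotation of GRCm38.p6, from which the coordinates given here were taken (counted from 1). Strand was not stated, so reads of overlapping or antisense genes could not be told apart, and the values of genes with near-identical copies (Hspa1b with Hspa1a, the Xlr3 genes, and pseudogene-rich families such as the ribosomal proteins) depend on how RSEM divided shared reads.

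Total expected counts ran from 16256305 to 19235226 per library. Expected counts were rounded to whole numbers. Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, its default filter on low counts by group (15012 genes kept), a robust quasi-likelihood fit over all 18 libraries, and 2-sided quasi-likelihood F tests for the contrasts high-fat minus control, delta-tocotrienol minus control and high-fat minus delta-tocotrienol. P-values were adjusted by Benjamini-Hochberg over all genes tested, the threshold was an adjusted p of 0.05, and there was no minimum fold. The common biological coefficient of variation was 0.225. Log2 CPM used a prior count of 2. CPM values are given as means and SDs over the 6 libraries of a group after TMM scaling. Standard errors of log2 fold changes were derived from the same fits.

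Before the data were examined, 36 gene lists were fixed, covering lipid, inflammatory, interferon, cell cycle, androgen, stress, clock, ribosomal and respiratory genes and markers of the cell types that dissected prostate could hold. Of these, 35 were tested, since the file carried none of the mitochondrially encoded genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The preset correlation is far below the correlations estimated here for most lists, so both results are given. The comparisons against control share the control libraries. The correlation of their fold changes was therefore set beside 20 simulations of unchanged groups and 20 splits of the controls into 3 and 3.

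The genes named were fixed by rule: in each comparison, up to 12 genes with the highest and 12 with the lowest log2 fold change among those that passed with a mean log2 CPM of at least 1 and an assigned symbol; where none passed in a direction, up to 5 of smallest p; from each list, up to 4 members of smallest p; and Pten, Hmgcr and Ar always. Any other gene named is said to have been chosen after its values were seen. The tests were run first on simulated counts drawn from the real means. In the simulation of high-fat against control, 51 of 100 genes changed 1.5-fold and 83 of 99 genes changed 2-fold were recovered, and 3 of 151 calls were false. For delta-tocotrienol against control these were 62 of 100, 92 of 100 and 4 of 158. For high-fat against delta-tocotrienol they were 127 of 200, 179 of 199 and 16 of 340. The simulated genes were drawn independently, with no outlying library, and changes were planted only in genes above a set mean level. These shares therefore do not show what the fits of the real libraries could detect.

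Alternatives chosen in advance were DESeq2 size factors, library totals, no filter and a stricter filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), a fit of only the 2 groups compared, 1 surrogate variable (sva 3.50.0), the replicate number as a block, a 2-fold minimum and leaving out each library in turn. The closing section names those added later and gives the effect of each. The surrogate variable stood at 0.95 in control 2 and between -0.13 and 0.08 in the other libraries. That fit is therefore close to leaving control 2 out and is not a separate check. For a library's length trend, relative transcript length was recovered from the ratio of expected count to TPM for 14922 genes (99.4% of those tested), and Spearman's rho was taken between it and the gene's log2 CPM less its mean over the libraries. The trend was removed as an offset fitted per library.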

Results

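Expression was measured by RNA sequencing in the prostate of male mice lacking Pten in the prostate, a tumour suppressor that opposes PI3K signalling. The labels describe the tissue as high-grade prostatic intraepithelial neoplasia. There were 18 libraries in 3 diet groups of 6, control, high-fat and delta-tocotrienol. Total expected counts were 16626875 to 18395099 in the control libraries, 16256305 to 18017274 in the high-fat libraries and 16291314 to 19235226 in the delta-tocotrienol libraries. After the filter on low counts, 15012 genes were tested. Pten transcripts were present in every library, at 124 ± 17.8 CPM (SD, n = 6) with control diet, 107 ± 6.09 CPM (SD, n = 6) with high-fat diet and 108 ± 10 CPM (SD, n = 6) with delta-tocotrienol. Expected counts per gene cannot show which exons remained, and no wild-type prostate was listed for comparison.

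The library labelled control 2 stood apart from the other 17. The first principal component of log2 CPM held 37.4% of the variance and placed control 2 at 120.4, with the second component at 14.1% of the variance. Its mean correlation across genes with the other 5 controls was 0.896, where the lowest value among those 5 was 0.975. The smooth muscle list averaged 9.86 log2 CPM in control 2 and 7.4 to 7.84 in the other controls, and the prostate secretory list 9.78 against 7.9 to 9.03. The luminal epithelium list averaged 7.76 in control 2 against 9.15 to 9.45, the list of NF-kB targets and cytokines 2.0 against 4.67 to 5.26, and the interferon response list 3.07 against 5.41 to 6.32. Tgm4, a secreted transglutaminase of prostate fluid, stood at 13.65 log2 CPM in control 2 and between 3.39 and 6.47 in the other controls. Pten stood at 7.3 log2 CPM in control 2 and between 6.56 and 6.96 in the other 17 libraries.

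**Figure D1:**
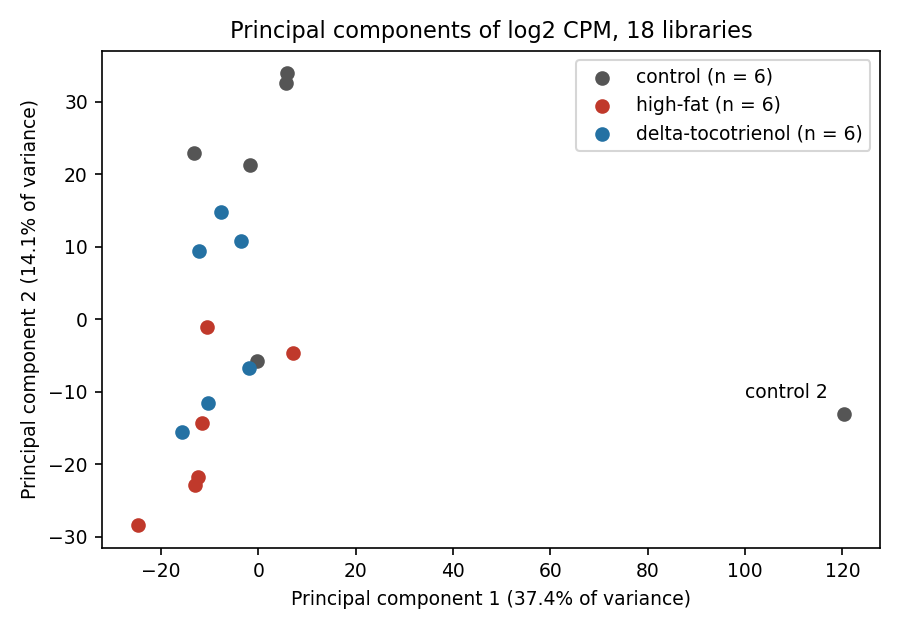
Principal components of log2 CPM over the 15012 tested genes, with the share of variance on each axis (37.4% and 14.1%) and 1 point per library, coloured by diet (n = 6 each). Control 2 lies at 120.4 on the first component, far from the other 17 libraries.

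The comparison of the high-fat with the control diet asked how a diet used to bring on metabolic syndrome related to expression in the Pten-deficient prostate. Genes of fatty acid synthesis, targets of the transcription factor SREBP1, fell in the high-fat group: 12 of the 18 measured members passed the test, all of them lower. Markers of endothelium, the lining of blood vessels, fell with them (8 of 11 members passed), and 5 of 16 markers of fibroblasts and their collagen matrix passed as lower. In camera with an estimated correlation the fatty acid, endothelium and fibroblast lists did not pass (adjusted p = 0.679 each). With fry the fibroblast list had an adjusted p of 0.0739 and the other lists named here 0.0175. Core circadian clock genes shifted in both directions, 4 higher and 2 lower of 15 measured. In all, 1866 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 786 higher (42.1%) and 1080 lower with the high-fat diet, and the median size of their log2 fold changes was 0.4.

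Among the fatty acid synthesis genes, Acaca encodes acetyl-CoA carboxylase, which carries out the first committed step (NCBI Gene 107476, GRCm38.p6 chromosome 11, 84129635 to 84401651). It stood at 35.7 ± 5.53 CPM (SD, n = 6) with the high-fat diet and at 121 ± 49.2 CPM (SD, n = 6) with control, a log2 fold change of -1.76 (SE 0.26; edgeR Benjamini-Hochberg adjusted p = 0.00646). Fasn, fatty acid synthase (chromosome 11, 120805958 to 120825166), stood at 318 ± 58.1 against 774 ± 317 CPM (SD, n = 6 each), a log2 fold change of -1.28 (SE 0.26; edgeR adjusted p = 0.0109). Scd1, the desaturase that makes monounsaturated fatty acids (chromosome 19, 44394450 to 44407709), stood at 479 ± 146 against 1490 ± 807 CPM (SD, n = 6 each), with -1.64 (SE 0.32; edgeR adjusted p = 0.0109). Thrsp, a regulator of lipogenesis (chromosome 7, 97412933 to 97417550), had the largest drop of the list, from 59.6 ± 41.7 to 10.2 ± 5.33 CPM (SD, n = 6 each), with -2.54 (SE 0.5; edgeR adjusted p = 0.0109). For each of these 4 genes, 6 of 6 high-fat libraries lay below the control median. The list's median log2 fold change was -0.99 and its camera adjusted p was 8.1e-07. With an estimated correlation between genes the adjusted p was 0.679, and fry, which asks only whether the members moved one way, gave an adjusted p of 0.0175. The count was also 12 when adjusted over the list alone. Without control 2 it was 8 and the median -0.65. The adipocyte marker list moved the same way, with a median of -0.8 (-0.48 without control 2) and all 14 members below 0 (camera adjusted p = 0.00173, or p = 0.679 with an estimated correlation). None of those 14 passed singly: Plin1, a protein of fat droplets, had -1.04 (SE 0.4; edgeR adjusted p = 0.0882) and Cidea -1.67 (SE 0.55; edgeR adjusted p = 0.0521). Cholesterol synthesis genes, the targets of the related factor SREBP2, did not follow: none of 25 passed, the median was 0.03 (camera adjusted p = 0.458), and Hmgcr, its rate-limiting enzyme, stood at 35.9 ± 7.18 against 35.6 ± 7.29 CPM (SD, n = 6 each).

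**Figure D2:**
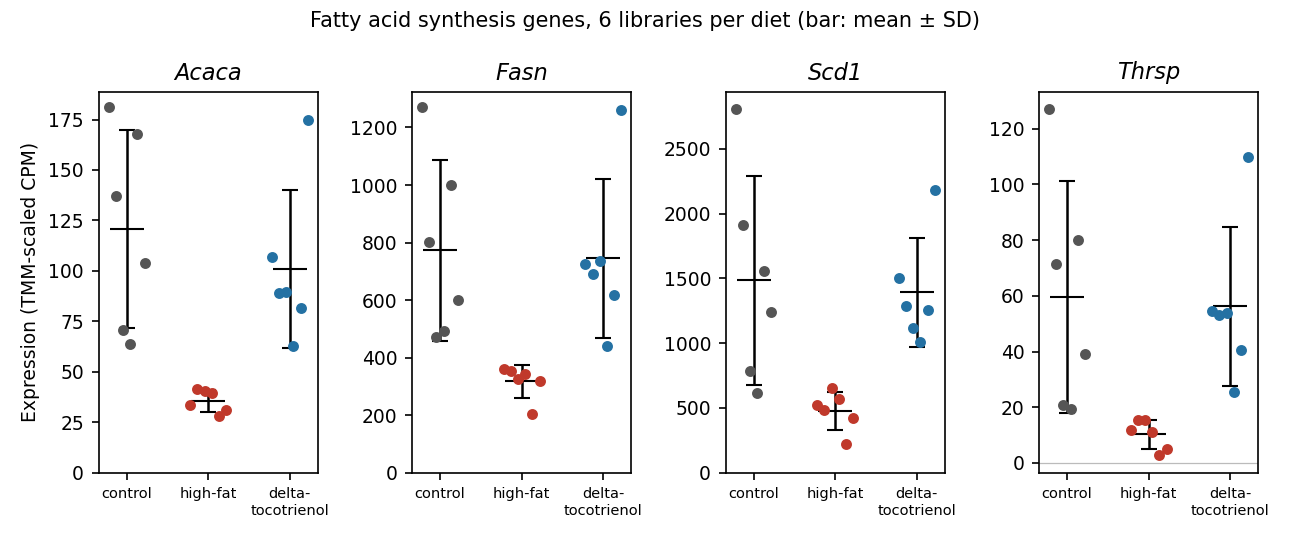
TMM-scaled CPM of Acaca, Fasn, Scd1 and Thrsp in each library by diet (points; n = 6 each), with the group mean and SD as bars. Acaca stands at 35.7 CPM on average in the high-fat group, below the means of 121 in the control group and 101 in the delta-tocotrienol group.

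Endothelial receptors were among the lower genes. The angiopoietin receptor Tek had a log2 fold change of -1.09 (SE 0.21), the VEGF receptor Kdr -1.02 (SE 0.2), Flt1 -0.97 (SE 0.22) and Tie1 -0.81 (SE 0.17), with edgeR Benjamini-Hochberg adjusted p of 0.0109, 0.0109, 0.0163 and 0.0119. The endothelium list had a median of -0.65 (camera adjusted p = 4.7e-07, or p = 0.679 with an estimated correlation; fry adjusted p = 0.0175), and all 11 members passed when adjusted over the list alone. Of the fibroblast list, Pdgfra, a receptor for platelet-derived growth factor, fell from 51.7 ± 13.1 to 21.7 ± 6.52 CPM (SD, n = 6 each; log2 fold change -1.25, SE 0.21, edgeR adjusted p = 0.00847), and Fbln1 (-1.05) and the proteoglycan Dcn (-0.7) fell too. All 16 members lay below 0, with a median of -0.73, and 11 passed when adjusted over the list alone. The camera adjusted p was 2.18e-06 (p = 0.679 with an estimated correlation), and the fry adjusted p 0.0739. The drop was not uniform over libraries. Control 1 (6.46 log2 CPM) and control 2 (6.63) lay within the high-fat range of 5.1 (high-fat 5) to 7.16 (high-fat 2). The other controls stood at 7.23 to 7.55. In the invasion and mesenchymal list, the transcription factors Zeb2 (-0.89) and Zeb1 (-0.64) were the 2 of 16 that passed (5 without control 2), with a list median of -0.54 (camera adjusted p = 0.00445, or p = 0.679 with an estimated correlation). Smooth muscle (median -0.81, none of 11 passed) and nerve and Schwann cell markers (median -0.68, 1 of 10 passed) also lay below 0, with camera adjusted p of 0.0118 and 0.0201. With an estimated correlation these were p = 0.679 for both. Without control 2 these 2 lists no longer passed, at medians of -0.13 and -0.31 and camera adjusted p of 0.172 and 0.128, and the nerve list also failed without high-fat 3, with mean differences in log2 CPM between -0.57 and -0.23 over the libraries left out. Macrophage markers had a median of -0.38 and 2 of 15 passed, Cd163 and Itgam (camera adjusted p = 0.111). Without control 2, 7 of these 15 were lower and the camera adjusted p was 9.48e-05 (p = 0.59 with an estimated correlation). With each library's length trend removed Zeb1 (-0.5), Cd163 (-1.15) and Itgam (-0.7) lost their calls.

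Clock genes of opposite phase moved apart. Per2, a repressor in the clock's feedback loop, stood at 35.6 ± 10.9 CPM against 12 ± 3.31 CPM with control (SD, n = 6 each; log2 fold change 1.57, SE 0.28, edgeR Benjamini-Hochberg adjusted p = 0.0102), and Per3 (0.94, SE 0.22), Dbp (1.31, SE 0.41) and Tef (0.74, SE 0.2) were higher with it. The activators Arntl and Clock fell, Arntl from 16.9 ± 5.35 to 8.47 ± 2.5 CPM (SD, n = 6 each; log2 fold change -1, SE 0.23, edgeR adjusted p = 0.0154) and Clock from 82.7 ± 4.65 to 63.8 ± 2.11 CPM (-0.37, SE 0.05, edgeR adjusted p = 0.00527; -0.17 with each library's length trend removed, edgeR adjusted p = 0.0328). Adjusted over the list alone, 7 were higher and 3 lower. As a list that moves both ways, its median of 0.27 did not pass (camera adjusted p = 0.0752). The labels give the daytime fast and no hour of collection per mouse. Without control 2, 6 were higher and 3 lower and the list passed (camera adjusted p = 0.0379, or p = 0.59 with an estimated correlation). Dbp lost its call when any of 9 of the 12 libraries was left out (log2 fold change 1.11 to 1.72) or the length trend removed (1.21), and Tef when any of 5 libraries was left out (0.64 to 0.93). With the adipocyte list mean as a covariate Per3 (0.81), Dbp (1.36), Tef (0.77) and Arntl (-0.76) lost their calls (edgeR adjusted p of 0.0746 to 0.109). Per2 (1.53) and Clock (-0.38) kept theirs.

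**Figure D3:**
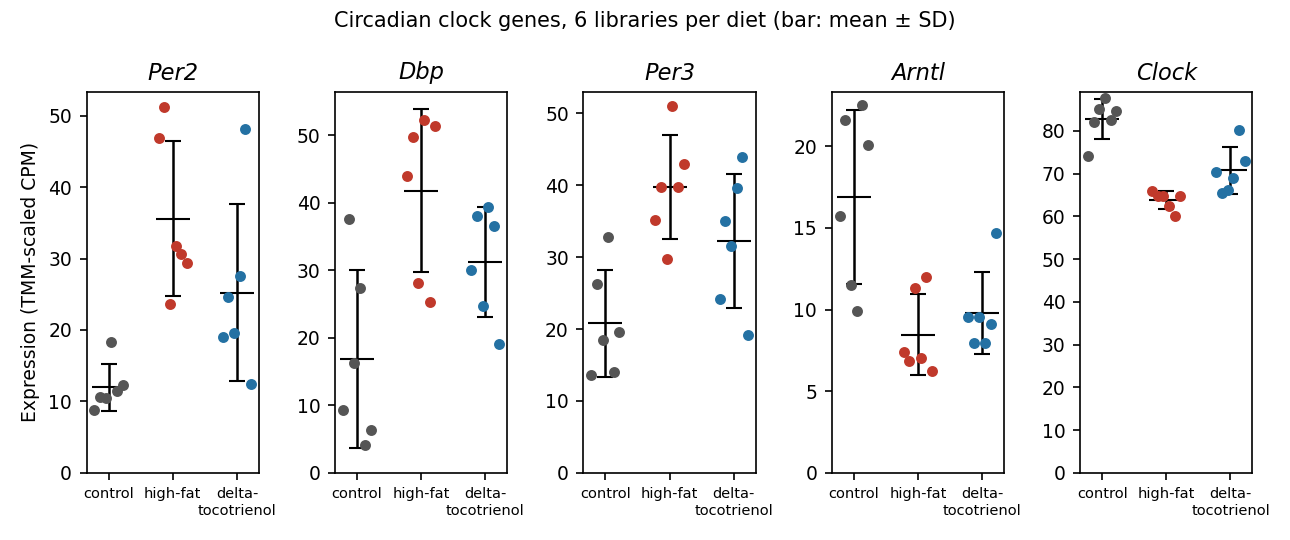
TMM-scaled CPM of the clock genes Per2, Dbp, Per3, Arntl and Clock in each library by diet (points; n = 6 each), with the group mean and SD as bars. Per2 averages 12 CPM with control and 35.6 CPM with the high-fat diet, and Arntl 16.9 and 8.47 CPM.

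Some luminal epithelial, stress, respiratory and ribosomal genes were higher with the high-fat diet. The luminal keratin Krt18 (log2 fold change 0.49, SE 0.12, edgeR Benjamini-Hochberg adjusted p = 0.0183) and the tight junction gene Cldn3 (0.5, SE 0.12, edgeR adjusted p = 0.0185) were the 2 of 11 luminal genes that passed (4 when adjusted over the list alone), and the list median was 0.37 (camera adjusted p = 0.00337, or p = 0.679 with an estimated correlation). Without control 2, 4 luminal genes were higher, but the mean difference of the list in log2 CPM fell from 0.41 to 0.15 and its median to 0.23 (camera adjusted p = 0.0662). In the basal list, Trp63 (-0.62) and Dst (-0.29) were lower, and the list did not pass (median -0.31, camera adjusted p = 0.358). Of 19 immediate-early and dissection stress genes, Jund (0.5), Junb (0.48) and the heat shock gene Hspa1b (2.28) passed, with a median of 0.34 (camera adjusted p = 0.00931, or p = 0.679 with an estimated correlation). The cell cycle list had a median of 0.2 and none of 30 passed (camera adjusted p = 0.00977, or p = 0.697 with an estimated correlation). Without control 2 its median was 0 and its camera adjusted p 0.693. Oxidative phosphorylation genes had a median of 0.19, with 5 of 25 higher, among them Ndufa1 (0.43) and Cox6c (0.35), and a camera adjusted p of 0.00118 (p = 0.679 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.23 and all 25 lay above 0, with 3 higher, Rpl27 (0.38), Rpl19 (0.32) and Rpl7 (0.28), and a camera adjusted p of 8.1e-07 (p = 0.679 with an estimated correlation). Without control 2, 24 of 25 ribosomal and 12 of 25 oxidative phosphorylation genes were higher. These last 2 lists hold mostly short transcripts, and short transcripts were higher as a class in the high-fat libraries. With each library's length trend removed, their mean differences in log2 CPM went from 0.16 to 0.02 and from 0.24 to 0.03, with camera adjusted p of 0.688 and 0.472, and Ndufa1 (0.16), Cox6c (0.08), Rpl27 (0.16), Rpl7 (0.09) and Rpl19 (0.1) were no longer called. Krt18 (0.36), Cldn3 (0.34), Trp63 (-0.51), Dst (-0.02), Junb (0.39) and Hspa1b (2.29) also lost their calls there, with edgeR adjusted p of 0.0509 to 0.864. Seminal vesicle genes, which mark a neighbouring gland, had a median of 2.33 with none of 9 passing (camera adjusted p = 0.0479, or p = 0.679 with an estimated correlation), and 2 passing without control 2. That call ended without any 1 of control 3, control 5, control 6, high-fat 2, high-fat 4 and high-fat 6, with mean differences between 1.48 and 2.67, and with the length trend removed (1.86, camera adjusted p = 0.0758). With 1 surrogate variable, which chiefly marked control 2, the calls of cell cycle (0.03, camera adjusted p = 0.636), luminal epithelium (0.15, 0.0556), smooth muscle (-0.16, 0.145) and nerve (-0.22, 0.119) ended. With the adipocyte covariate those of cell cycle (0.03, camera adjusted p = 0.647), smooth muscle (-0.1, 0.588) and nerve (-0.37, 0.0695) ended.

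Single genes of other functions passed as well. Taldo1, an enzyme of the pentose phosphate pathway, was higher (0.44, SE 0.07, edgeR Benjamini-Hochberg adjusted p = 0.00821), the 1 of 18 NRF2 antioxidant genes to pass. Of 12 measured vitamin E and xenobiotic genes, Sec14l2, which binds tocopherol, was higher (0.44, SE 0.12), and Abcb1a (-0.96), Cyp1b1 (-0.9) and Scarb1 (-0.5) were among the 4 lower. In the PI3K and FOXO list, Txnip (0.34) and the insulin receptor Insr (-0.2) passed, but with the length trend removed neither did, Txnip at an unchanged 0.34 and Insr at 0.01 (edgeR adjusted p of 0.0804 and 0.904). The androgen-responsive genes Ndrg1 (-0.52) and Camkk2 (-0.45) were lower while the androgen receptor Ar stood at 136 ± 18.2 against 138 ± 15.7 CPM (SD, n = 6 each; edgeR adjusted p = 0.9). The p53 target Cdkn1a (-0.29), the B cell gene Ms4a1 (-1.82) and Pmp22 of nerve (-0.68) were lower, and Acot2 (0.35) and Xbp1 (0.29), of the fatty acid oxidation and unfolded protein lists, were higher. With the length trend removed Taldo1 (0.29) was still called, and Camkk2 (-0.33), Cyp1b1 (-0.77), Ms4a1 (-1.88), Acot2 (0.3) and Xbp1 (0.24) were not. Pten had -0.2 (SE 0.08; edgeR adjusted p = 0.107).

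Several of the genes of largest fold depended on control 2. Among the 12 highest, Hspa1b (241 ± 363 against 49.4 ± 10.1 CPM, SD, n = 6 each) was followed by Smgc (1.8), Per2, Ptx3 (1.53), Xlr3c (1.45), Dbp, Per3, Smco4 (0.85), Fbp2 (0.81), Rad51c (0.8), Hspa8 (0.78) and Tef. Among the 12 lowest, Tgm4 stood at 20.2 ± 10.3 against 2190 ± 5240 CPM (SD, n = 6 each), a log2 fold change of -6.76 (SE 1.7; edgeR Benjamini-Hochberg adjusted p = 0.022), and at -1.15 without control 2 (edgeR adjusted p = 0.197). Likewise Chn2 went from -4.1 to -0.13, Gsdma from -3.31 to 0.13, Grid1 from -1.99 to -1, Vash2 from -2.12 to -1.18, Fam167a from -1.91 to -1.06, Pax8 from -1.9 to -0.98 and Pnpla3, of the fatty acid list, from -1.82 to -1.6, and none of these 7 passed without control 2 (edgeR adjusted p of 0.0536 to 0.723). Tcaf3 (-3.98 to -1.58), Klf12 (-2.63 to -1.02) and Col4a6 (-2.14 to -0.69) passed without it, with edgeR adjusted p of 0.0343, 0.00573 and 0.0235. Of the 66 named genes that passed, 25 did so with each of the 12 libraries left out in turn, among them Acaca, Scd1, Fasn, Thrsp, Kdr, Tek, Pdgfra, Per2, Arntl, Clock, Krt18, Zeb2 and Taldo1. The other 41 lost the call in at least 1 such fit, and Gsdma alone changed direction. Of the 66 calls, 38 were lost without high-fat 1, 32 without high-fat 6, 31 without high-fat 4, 29 without high-fat 5, 29 without control 5, 25 without control 6, 17 without high-fat 3, 14 without high-fat 2, 14 without control 4, 13 without control 2, 10 without control 3 and 6 without control 1. With each library's length trend removed 30 of the 66 were still called. Hspa1b lost its call when any of 9 libraries was left out, at 0.96 to 2.52, Hspa8 and Trp63 without high-fat 1 (lowest and highest values 0.64 and 0.85, and -0.68 and -0.56), Cdkn1a without high-fat 6 (-0.34 and -0.25), and Jund and Rad51c without control 5 or high-fat 1 (0.39 and 0.59, and 0.64 and 0.98).

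The remaining lists did not pass in this comparison, with camera adjusted p between 0.0592 and 0.888. Their median log2 fold changes were 0.21 for the unfolded protein and integrated stress response, 0.12 for NF-kB targets and cytokines, 0.12 for the interferon response, 0.1 for the NRF2 list (mean -0.01), 0.13 for glycolysis and hypoxia, 0.25 for urothelium, 0.1 for neutrophils and 0.23 for the prostate secretory genes, whose mean was -0.52. They were -0.17 for the PI3K and FOXO list, -0.17 for androgen-responsive genes, -0.12 for vitamin E and xenobiotic genes, -0.04 for fatty acid oxidation, -0.05 for p53 targets, -0.49 for neuroendocrine cells, -0.23 for T and NK cells, -0.21 for B and plasma cells, -0.24 for skeletal muscle and -0.18 for erythroid cells. Without control 2 the medians changed sign for NF-kB targets (-0.03), the interferon response (-0.08), neutrophils (-0.1), skeletal muscle (0.21), erythroid cells (0.01) and cholesterol synthesis (-0.05), and neuroendocrine cells (-0.06), glycolysis (0.01) and androgen-responsive genes (-0.01) lay near 0. Without it the unfolded protein list had 6 members higher and 1 lower (camera adjusted p = 0.00051, or p = 0.59 with an estimated correlation) and the secretory list passed at a median of 0.41 (camera adjusted p = 0.0354, or p = 0.59 with an estimated correlation).

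The edgeR quasi-likelihood test passed 2793 genes without control 2 (1431 higher, 1362 lower), of which 1634 had passed in the same direction with it. Fits without another single library passed 2902 genes (control 1), 843 (control 5), 968 (control 6), 675 (high-fat 1), 1127 (high-fat 4), 863 (high-fat 5) and 1020 (high-fat 6), and the share of higher calls fell from 42.1% to 18.1% with library totals in place of TMM (365 of 2018) and to 24.8% with limma-trend on log2(FPKM + 1) (396 of 1594). Changes of at least 2-fold numbered 218, of which 206 were lower (131 and 112 without control 2), and 614 genes passed with each library's length trend removed, 531 in a fit of only these 2 groups, 378 with the adipocyte list mean as a covariate and 0 with the fibroblast list mean as a covariate (edgeR; 2836 at an unadjusted p under 0.05).

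The comparison of delta-tocotrienol with control asked how this form of vitamin E, given in the control diet, related to expression in the same tissue. No single gene passed edgeR's test. Of the fixed lists 11 passed camera, none of them with an estimated correlation (p = 0.732 for each). Endothelial markers lay below 0 in 11 of 11 members, with a median log2 fold change of -0.6, and fibroblast markers in 15 of 16, with a median of -0.45. Genes of the interferon response lay above 0 in 22 of 22 members (median 0.51), and 28 of 30 cell cycle genes and 21 of 25 oxidative phosphorylation genes lay above 0 (medians 0.25 and 0.17). The fatty acid synthesis list, lower with the high-fat diet, had a median of -0.09 here (camera adjusted p = 0.308).

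In the endothelium list, Pecam1 stood at 32.6 ± 4.5 CPM with delta-tocotrienol and 48.8 ± 14.3 CPM with control (SD, n = 6 each; log2 fold change -0.58, SE 0.16, edgeR Benjamini-Hochberg adjusted p = 0.0915), and Kdr had -0.71 (SE 0.2; edgeR adjusted p = 0.0921). All 11 passed when adjusted over the list alone, and the camera adjusted p was 6.53e-07 (p = 0.732 with an estimated correlation). Pdgfra of the fibroblast list stood at 28.4 ± 7.41 against 51.7 ± 13.1 CPM (SD, n = 6 each; log2 fold change -0.87, SE 0.21, edgeR adjusted p = 0.0878). In that list 1 member passed when adjusted over the list alone, and the camera adjusted p was 0.00305 (p = 0.732 with an estimated correlation). Nerve and Schwann cell markers had a median of -0.72, with Nefm at -1.26 and the myelin gene Mpz at -1.13, 8 of 10 lower when adjusted over the list alone, and a camera adjusted p of 0.00161 (p = 0.732 with an estimated correlation). Without control 2 that median was -0.31, Nefm had -0.89, Mpz -0.56, and the camera adjusted p was 0.0225 (p = 0.654 with an estimated correlation). Smooth muscle had a median of -0.71 (camera adjusted p = 0.0339, or p = 0.732 with an estimated correlation), which ended without control 1, control 2, delta-tocotrienol 1 or delta-tocotrienol 3 (mean differences in log2 CPM of -0.51 to -0.02).

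Interferon genes included Xaf1 at 24.9 ± 6.45 against 17 ± 6.26 CPM and the antiviral tetherin Bst2 at 64.3 ± 16.7 against 45.4 ± 14.9 CPM (SD, n = 6 each), with log2 fold changes of 0.55 and 0.5 and edgeR Benjamini-Hochberg adjusted p of 0.19 and 0.2. The interferon list had a camera adjusted p of 0.000131 (p = 0.732 with an estimated correlation). Its mean difference in log2 CPM was 0.69, and 0.21 without control 2, where interferon genes were low (camera adjusted p = 0.0301, or p = 0.78 with an estimated correlation). The thymidylate synthase gene Tyms (0.34) and Mcm2 (0.22) of the cell cycle list did not pass singly, and the list's camera adjusted p was 5.67e-05 (p = 0.732 with an estimated correlation), with a mean difference of 0.36, and of 0.11 without control 2 (camera adjusted p = 0.0401, or p = 0.78 with an estimated correlation). Luminal epithelium (median 0.24, Cldn3 0.33, camera adjusted p = 0.0175) and immediate-early genes (median 0.26, Junb 0.38, camera adjusted p = 0.0114) had p = 0.732 with an estimated correlation, and neither passed without control 2, where their mean differences in log2 CPM went from 0.31 to 0.06 and from 0.35 to 0.24 (camera adjusted p of 0.392 and 0.0554). The NRF2 antioxidant list had a median of 0.1, with Taldo1 at 0.33 (SE 0.07; edgeR adjusted p = 0.0878) passing when adjusted over the list alone. Its camera adjusted p was 0.0376 (p = 0.732 with an estimated correlation), and the call ended without control 4, control 5, control 6 or delta-tocotrienol 1 (mean differences of 0.06 to 0.14). Oxidative phosphorylation, with Ndufa1 at 0.41, and ribosomal protein genes (median 0.15) each had a camera adjusted p of 5.67e-05 (p = 0.732 with an estimated correlation). With each library's length trend removed their mean differences were 0.05 and 0, with camera adjusted p of 0.1 and 0.93, and those of the luminal and NRF2 lists 0.24 (0.0713) and 0.04 (0.165). With 1 surrogate variable, which chiefly marked control 2, the calls of interferon (0.13, camera adjusted p = 0.147), cell cycle (0.08, 0.166), luminal epithelium (0.01, 0.682), smooth muscle (0.06, 0.62), NRF2 (0.1, 0.0777) and immediate-early genes (0.24, 0.0942) ended. With the adipocyte covariate that of smooth muscle ended (-0.3, camera adjusted p = 0.0571).

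Of the clock genes, Per2 had 1.07 (SE 0.27) and Clock -0.23 (SE 0.05), both with an edgeR Benjamini-Hochberg adjusted p of 0.0878. When adjusted over the list alone 3 were higher and 2 lower, and the list did not pass (median 0.16, camera adjusted p = 0.105). The genes of smallest p were Rapgef6 (-0.41), Ern1 (-0.8), a sensor of unfolded protein, Zyg11b (-0.45), Dock1 (-0.53) and Kif21a (-0.45) among the lower, and Bud23 (0.28), H2afj (0.46), Psma7 (0.33), Tmem14c (0.33) and Ap1m2 (0.33) among the higher, with edgeR adjusted p of 0.0696 to 0.0878. These 10 passed in the fit without control 1 and in no other fit with a library left out. Hmgcr, whose protein tocotrienols are known to destabilise, stood at 35.2 ± 5.03 against 35.6 ± 7.29 CPM, Pten at 108 ± 10 against 124 ± 17.8 CPM and Ar at 131 ± 12.4 against 138 ± 15.7 CPM (SD, n = 6 each). The other 24 lists, those of cholesterol synthesis (median 0.06, and -0.03 without control 2) and of vitamin E and xenobiotic genes (median -0.25, and -0.15) among them, had camera adjusted p between 0.0506 and 0.976. Of these, 6 passed without control 2: macrophages (median -0.24, camera adjusted p = 0.000507), the unfolded protein list (0.21, 0.00493), the secretory list (0.41, 0.0401), basal epithelium (-0.3, 0.0401), the clock list (0.3, 0.0401) and the invasion list (-0.22, 0.0481). They had p = 0.654 (macrophages and clock) or p = 0.78 with an estimated correlation. Medians and tests differed in sign for neutrophils (median -0.22, camera direction up) and p53 targets (-0.01, up), and median and mean for the secretory list (0.16 and -0.59) and fatty acid oxidation (0.01 and -0.05).

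With edgeR's quasi-likelihood test 0 genes passed and 3207 (21.4%) had an unadjusted p under 0.05, whereas DESeq2 passed 586 (268 higher, 318 lower), limma-voom with sample quality weights 2175 and limma-trend on log2(FPKM + 1) 0. Without control 1 the edgeR count was 987 (442 higher, 545 lower), and without control 2 it was 0, with 3377 genes at an unadjusted p under 0.05.

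Both diet comparisons used the same 6 controls, and their fold changes ran in parallel. Across all 15012 genes Pearson's r was 0.819, Spearman's rho 0.844 and the covariance 0.122, and 86.2% of genes had the same sign. Genes are not independent replicates, so these values carry no p. Counts simulated for all 18 libraries with unchanged groups, controls included, gave a mean r of 0.506 (0.486 to 0.534). Their covariance was 0.027 with 66.6% of signs shared, and the observed covariance exceeded it by 0.095. The real controls' own spread, taken from the libraries, gives a covariance of 0.0448. That is above the simulated one, so the excess of 0.095 overstates a shared response. With the controls split 3 and 3, so that the comparisons shared none, the median r over 20 splits was 0.313 (0.164 to 0.431) and the median covariance 0.0476. Without control 2, r was 0.689 and the covariance 0.063, where the spread of the other 5 controls gives 0.0232. Calls in both comparisons numbered 0, as the delta-tocotrienol comparison had none. Yet of the 1866 genes called with the high-fat diet, 1865 (99.9%) had the same sign with delta-tocotrienol. Of these, 1503 had an unadjusted p under 0.05 there (edgeR). Among the 1866, the median ratio of log2 fold changes, delta-tocotrienol over high-fat, was 0.73. The test that called these genes used the same controls, which by itself favours the same sign. The calls are therefore not shown to be particular to the high-fat diet.

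Fold changes of both diets against control ran with transcript length. With genes placed by transcript length in 4 bins of nearly equal number, median log2 fold changes in high-fat against control were 0.16, 0.05, -0.03 and -0.14 from shortest to longest, and with delta-tocotrienol 0.13, 0.04, -0.03 and -0.12. Per library, Spearman's rho of expression with length across genes averaged 0.23 ± 0.25 in controls, -0.22 ± 0.03 with the high-fat diet and -0.13 ± 0.21 with delta-tocotrienol (SD, n = 6 each). An exact 2-sided permutation test over 924 regroupings gave p = 0.00216 for high-fat, 0.026 for delta-tocotrienol and 0.325 for the 2 diets against each other, or 0.00648, 0.039 and 0.325 after Benjamini-Hochberg adjustment over these 3. Among the controls, control 1 had -0.18, control 2 0.06, control 3 0.22 and the other 3 had 0.4 to 0.47.

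**Figure D4:**
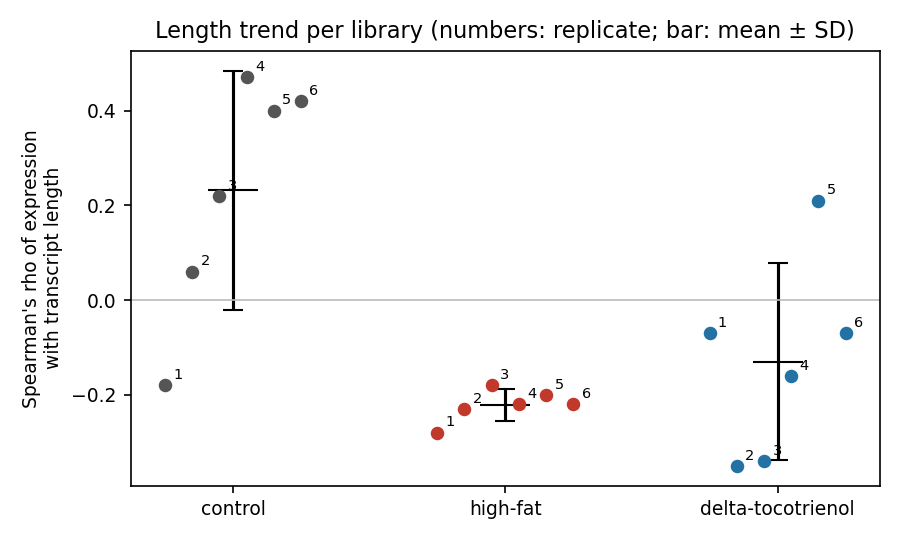
Spearman's rho between relative transcript length and expression (log2 CPM less each gene's mean over libraries) in each library by diet (points, numbered by replicate), with the group mean and SD as bars (n = 6 each). High-fat libraries lie between -0.28 and -0.18, and controls between -0.18 and 0.47.

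The comparison of high-fat with delta-tocotrienol set the diets against each other without the control libraries in the contrast. No single gene passed edgeR's test, and of 12 lists that passed camera 3 did so with an estimated correlation. These were fatty acid synthesis, with 17 of 18 members below 0 and a median log2 fold change of -0.55, T and NK cells, with 10 of 10 below 0 (median -0.33), and urothelium, the lining of the bladder and urethra, with 6 of 7 above 0 (median 0.53). Interferon genes lay below 0 in 21 of 22 (median -0.34) and adipocyte markers in 13 of 14 (median -0.48), and neither list passed with an estimated correlation (p = 0.901 and p = 0.706).

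Acaca stood at 35.7 ± 5.53 CPM with the high-fat diet and 101 ± 38.9 CPM with delta-tocotrienol (SD, n = 6 each), a log2 fold change of -1.5 (SE 0.26; edgeR Benjamini-Hochberg adjusted p = 0.309). Thrsp had -2.45 (SE 0.5), Scd1 -1.54 (SE 0.32) and Fasn -1.23 (SE 0.26), each with an edgeR adjusted p of 0.466, and in each of the 4 genes 6 of 6 high-fat libraries lay below the delta-tocotrienol median. Adjusted over the list alone 9 of 18 were lower, and the camera adjusted p was 4.97e-19 (p = 0.047 with an estimated correlation, fry adjusted p = 0.0948). In the urothelium list Upk2 stood at 21.2 ± 3.56 against 14.7 ± 2.94 CPM and Upk1b at 93.8 ± 29.8 against 74.1 ± 10.9 CPM (SD, n = 6 each). Of its members 1 was higher when adjusted over the list alone, and its camera adjusted p was 2.26e-05 (p = 0.047 with an estimated correlation). Of the T and NK cell list, Cd3d stood at 0.421 ± 0.221 against 0.823 ± 0.252 CPM and Il2rb at 3.73 ± 1.21 against 5.1 ± 1.07 CPM (SD, n = 6 each). Its camera adjusted p was 2.05e-06 (p = 0.047 with an estimated correlation). These 3 lists were the ones that held with an estimated correlation, and they no longer did when control 2 was left out of the estimate of spread (p = 0.152 for each).

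Interferon genes, with Rsad2 at -0.9, had a camera adjusted p of 0.00078 (p = 0.901 with an estimated correlation), and Cxcl10, an interferon-induced chemokine of the cytokine list, had -1.42. Fibroblast markers (median -0.32, Fbln1 -0.5, Pdgfra -0.39) and adipocyte markers (Cidea -1.76, Cfd -1.44) each had a camera adjusted p of 1.52e-06, with p = 0.736 and p = 0.706 with an estimated correlation. The secreted phosphoprotein Spp1 stood at 24.2 ± 6.33 against 49.3 ± 5.75 CPM (SD, n = 6 each). Its list, that of invasion, had a median of -0.32 and a camera adjusted p of 0.000403 (p = 0.706 with an estimated correlation). Ribosomal protein genes had a median of 0.07 (camera adjusted p = 0.00122), a call that ended without high-fat 5 (mean differences of 0.04 to 0.09) and with the length trend removed (0.03, camera adjusted p = 0.23). Endothelium (-0.13, camera adjusted p = 0.0207), luminal epithelium (0.12, 0.0479), the unfolded protein list (0.1, 0.0299) and seminal vesicle genes (1.31, with Sva at 112 ± 163 against 31.9 ± 41 CPM, SD, n = 6 each; camera adjusted p = 0.0122) each ended without any of 5 or 6 single libraries. All of these 5 had p = 0.901 with an estimated correlation. With the length trend removed luminal epithelium (0.08, camera adjusted p = 0.116) and the unfolded protein list (0.1, 0.0638) also ended, as did the latter with 1 surrogate variable (0.09, 0.135) and luminal epithelium (-0.04, 0.785) and endothelium (0.05, 0.498) with the adipocyte covariate. The other 23 lists had camera adjusted p from 0.0659 to 0.974. With control 2 left out of the fit, cell cycle (median -0.09, camera adjusted p = 0.0132), macrophages (-0.12, 0.0271) and smooth muscle (-0.14, 0.0366) passed, with p = 0.799 each with an estimated correlation. For NF-kB targets, neutrophils, basal epithelium, glycolysis and vitamin E genes the median and the camera direction differed in sign, at medians of 0.04, 0.04, -0.05, 0.01 and 0.01.

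No gene passed edgeR's quasi-likelihood test in this comparison (0 of 15012). An unadjusted p under 0.05 was reached by 393 genes (2.6%), below the share of 0.05 that unchanged genes would give on average. With control 2 left out of the fit, 765 (5.1%) reached it. The number was 887 in an edgeR fit of only these 2 groups, 824 with 1 surrogate variable and 1022 in limma-voom with sample quality weights, each with 0 genes passing. The count of 0 therefore does not show that expression was alike in the 2 diets. DESeq2 passed 6, all lower, of which 4 were Acaca, Thrsp, Scd1 and Fasn (DESeq2 adjusted p of 0.000157, 0.00732, 0.00728 and 0.00732) and the others Evl (0.0126) and Evi2 (0.0182), the last chosen after its values were seen. Limma-voom with sample quality weights and limma-trend on log2(FPKM + 1) passed 0. The remaining genes of smallest p were Chmp5 (0.19), Mrpl36 (0.27), BC005624 (0.17), Gpatch4 (0.3) and Ap4b1 (0.29), all with an edgeR adjusted p of 1, and Pten, Hmgcr and Ar had log2 fold changes of -0.01, 0.03 (-0.02 with library totals) and 0.06.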

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

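Of the tests in this part, those of stroma and of Pten in control 2, those with the length trend removed or with the adipocyte or fibroblast list mean as a covariate, both counts of splits at an unadjusted p under 0.05, and the levels given for Cfd, Plin4 and Fabp4 were chosen only after the result was seen. A library was singled out when its gap to the nearest of its group exceeded the 95% critical share of the group's range (Dixon), which chance does in about 1 in 20 groups. This happened in 1 of 12 groups of library measures, 13 of 105 groups of list means and 29 of 223 groups of named genes, where chance gives about 1, 5 and 11, and control 2 was the library in 1, 10 and 15 of them. The named genes were chosen from these data, some for folds that rested on control 2, so their 29 cannot be set against 11. The lists run together within a library, so their 105 groups are not independent.

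Control 2 held 17.02% of its counts in its 10 most abundant genes (other controls 7.01 to 8.05). Its list means in log2 CPM were high for smooth muscle (9.86; others 7.4 to 7.84) and skeletal muscle (8.54; 6.63 to 7.07). They were low for NF-kB targets (2.0; 4.67 to 5.26), interferon response (3.07; 5.41 to 6.32), cell cycle (2.12; 3.33 to 3.92), luminal epithelium (7.76; 9.15 to 9.45), macrophages (3.94; 4.96 to 5.5), p53 targets (4.43; 4.92 to 5.1), glycolysis (6.55; 7.29 to 7.57) and immediate-early genes (4.96; 5.5 to 5.69). Among genes, in log2 CPM, Tgm4 (13.65; others 3.39 to 6.47), Chn2 (9.31; 2.33 to 3.39), Tcaf3 (9.04; 2.61 to 4.9), Gsdma (9.5; 2.95 to 3.86), Klf12 (5.2; 1.11 to 1.76), Col4a6 (7.7; 3.78 to 4.55), Grid1 (4.54; 1.04 to 2.3), Pten (7.3; 6.75 to 6.95), Scarb1 (6.44; 5.42 to 5.75) and Mpz (5.9; 3.59 to 4.3) were high. Hmgcr (4.45; 5.14 to 5.37), Cldn3 (7.81; 8.46 to 8.85), Junb (6.08; 7.08 to 7.37), Xaf1 (2.7; 3.88 to 4.56) and Bst2 (4.14; 5.36 to 5.87) were low.

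More stroma and less epithelium in the dissected piece would lower secretory and luminal genes of control 2 alike, yet the median of the secretory list lay 2.15 above the other controls and that of the luminal list fell by 1.1, a parting of 3.24 (log2), or 8.5 times the SD of 0.38 over the other 17 libraries, which argues against it as the whole cause. Without its 50 most abundant genes the mean correlation of control 2 with the other controls was 0.895, and the lowest among those was 0.974. The low correlation therefore did not rest on those 50 genes themselves. Whether a few abundant genes took counts from the rest stays undecided. So few genes hardly weigh in a correlation, which also ignores a shift common to the others. Pten not deleted, or deleted in few cells, stays open: Pten in control 2 lay 0.35 (log2 CPM) above the highest of the other 17 libraries (7.3 against 6.96) and the cell cycle list below the lowest (2.12 against 3.33), but smooth muscle and endothelium (4.7; other controls 3.67 to 4.29), where a prostate-specific deletion would leave Pten intact, were high as well. Other cells that would keep Pten were not high: the fibroblast list stood at 6.63 (other controls 6.46 to 7.55) and the macrophage list at 3.94 (4.96 to 5.5). A sample of another genotype or another piece of the gland, or a wrong label, could give the same values, and no library from a mouse with intact Pten was listed to test this.

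The length trend of the diet groups had a Spearman's rho of log2 fold change with transcript length of -0.43 with the high-fat diet and -0.41 with delta-tocotrienol. Length-dependent recovery of reads could account for much of it: with each library's length trend removed, calls in high-fat against control went from 1866 to 614, of which 506 were among the 1866, and the median size of the fold changes of the 1866 genes went from 0.4 to 0.29 at a median SE of 0.1 in both fits, with 99.2% keeping their direction. Smaller fold changes do not account for each lost call: those of Hspa1b (2.28 and 2.29 with the trend removed) and Chn2 (-4.1 and -4.11) ended without one. Their edgeR adjusted p lay near the threshold, at 0.0481 and 0.0732 for Hspa1b and 0.0329 and 0.0521 for Chn2. Genes at an unadjusted p under 0.05 went from 4675 to 3673 (edgeR), and the adjustment of each gene depends on all genes tested. How much of the lost calls this gives was not tested. Whether fewer fibroblasts in the diet groups were the whole cause of the length trend stays undecided. Rho was -0.32 with the fibroblast list mean as a covariate. A mean of marker genes follows fibroblast content only in part, so some trend could remain even then. Control 2 alone is argued against, since rho was -0.49 without it (-0.5 with delta-tocotrienol). For the calls in high-fat against control fibroblast content is not set aside either. With that covariate 0 genes passed (edgeR, with 2836 at an unadjusted p under 0.05). An effect of diet on long transcripts stays open and was not tested, as no value in these libraries parts it from recovery.

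Fatty acid synthesis genes lower with the high-fat diet are not explained by the length trend, since the median log2 fold change of the 12 called members was -1.25 (median SE 0.3) and -1.17 (0.31) with that trend removed, where all 12 had an unadjusted p under 0.05 and 6 were still called. Less adipose tissue in the high-fat libraries could not be told apart from less lipogenesis: with the adipocyte list mean as a covariate the median was -0.63 (median SE 0.26), 9 of 12 had an unadjusted p under 0.05 and 2, Acaca (-1.27) and Thrsp (-1.48), were still called. The mean difference of the whole fatty acid list in log2 CPM went from -0.84 to -0.5 with it (camera adjusted p = 3.39e-05 at the preset correlation). The adipocyte list averaged 5.44 ± 0.87 log2 CPM with control, 4.48 ± 0.92 with high-fat and 5.23 ± 0.37 with delta-tocotrienol (SD, n = 6 each), and shared 0 members with the fatty acid list. Of its abundant genes, Fabp4 stood at 96.1 ± 38.2 CPM with high-fat and 156 ± 92 CPM with control, Cfd at 54.6 ± 49.1 and 141 ± 70.5 CPM, and Plin4 at 51 ± 22.7 and 92.1 ± 71.5 CPM (SD, n = 6 each). A response of the epithelium to the diet stays open and was not tested.

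In the other libraries, cholesterol synthesis (4.98; other high-fat libraries 5.36 to 5.53), Tgm4 (1.39; 3.74 to 4.82), Tcaf3 (-0.01; 2.24 to 3.43), Hmgcr (4.53; 5.13 to 5.46), Fasn (7.67; 8.32 to 8.5) and Upk2 (3.86; 4.41 to 4.62) were low, and Ar (7.43; 6.96 to 7.08) and Rpl7 (9.69; 9.34 to 9.44) high, in high-fat 5. Smgc was low in high-fat 3 (0.02; 2.02 to 3.17) and Txnip high in high-fat 1 (10.2; 9.67 to 9.86). In control 1 the PI3K and FOXO list (5.84; 6.04 to 6.15) and Dock1 (5.12; 5.45 to 5.55) were low, and Rad51c (1.63; 0.64 to 0.93) and Hspa8 (10.44; 10.18 to 10.23) high. Smooth muscle was low in delta-tocotrienol 3 (7.15; 7.55 to 7.73), Cidea in delta-tocotrienol 4 (2.31; 3.72 to 4.54) and Cldn3 in delta-tocotrienol 5 (8.6; 8.82 to 8.93).

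In high-fat against delta-tocotrienol, 12 lists passed camera at its preset correlation. Medians and camera adjusted p were -0.55 and 4.97e-19 (fatty acid synthesis), -0.34 and 0.00078 (interferon) and 1.31 and 0.0122 (seminal vesicle). They were 0.53 and 2.26e-05 (urothelium), 0.12 and 0.0479 (luminal epithelium) and -0.33 and 2.05e-06 (T and NK cells). For fibroblasts they were -0.32 and 1.52e-06, for adipocytes -0.48 and 1.52e-06 and for endothelium -0.13 and 0.0207. For the unfolded protein response they were 0.1 and 0.0299, for invasion -0.32 and 0.000403 and for ribosomal proteins 0.07 and 0.00122. With an estimated correlation, 3 of these passed, those of fatty acid synthesis, urothelium and T and NK cells (p = 0.047 each). With control 2 left out of the estimate of spread, 0 lists passed that test, and 0 passed fry with all libraries. As many lists as 12 also came from 33 of 100 regroupings of the libraries, described next. Whether the effects of the 2 diets differed in these lists is therefore not settled.

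Regroupings of the 12 libraries of each comparison, 100 drawn with the real one included, showed which counts chance gives. For high-fat against control, 1 of 100, the real one, gave as many genes as 1866 (highest other 741). Chance is thus unlikely for the gene count, though 100 regroupings cannot exclude it. As many lists as 13 came from 72 of them (highest other 22), so chance could give the count of lists. For delta-tocotrienol against control, 85 of 100 gave as many lists as 11 (highest other 22), so chance is not excluded for the lists, while 1 of 100, the real one, gave as many as 3207 genes at an unadjusted p under 0.05 (highest other 2919). For high-fat against delta-tocotrienol, 33 gave as many lists as 12 (highest other 16) and 30 as many as 393 genes at an unadjusted p under 0.05 (highest other 1164; 765 with control 2 left out of the fit, not set against regroupings), so chance is not excluded for either. The edgeR counts of 0 genes in these last comparisons (3207 and 393 at an unadjusted p under 0.05; DESeq2 586 and 6) cannot be tested this way, since each of the 100 regroupings gives at least 0 (highest other 0 in both).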

How the results depend on the processing

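The alternatives chosen only after the data were seen were those with the length trend removed (with and without control 2), with the adipocyte or fibroblast list mean as a covariate, with an estimated correlation without control 2, and the overlap without control 2. In high-fat against control, 1866 genes passed, 1842 with DESeq2 size factors, 2018 with library totals, 1503 without the filter, 1875 with a strict filter and 2611 with DESeq2. Limma-trend on FPKM gave 1594 and 1615 (pseudocounts of 1 and 0.1) and a replicate block 1463. Replicate numbers did not pair most of the libraries (r of -0.21 to 0.32, with 4 of 18 closest to their own number). In each pair of groups, though, the library numbered 2 was closest to its own number (r of 0.32, 0.24 and 0.17), and why was not tested. The count in high-fat against control was 218 with a 2-fold minimum, which asks for more by construction (131 without control 2). It was 3796 with voom quality weights, which gave control 2 a weight of 0.08, and 2887 with 1 surrogate variable (0.95 in control 2). A fit of only the 2 groups compared gave 531, with the spread taken from those libraries alone. With the length trend removed the count was 614, and 902 with control 2 also left out. The adipocyte covariate gave 378 and the fibroblast covariate 0 (edgeR, with 2836 at an unadjusted p under 0.05). With 1 library left out the count was 675 to 2902. For the fit of 2 groups, the covariates and the libraries left out the cause was not tested. Of 66 named genes called, 63 kept their direction in every setting run, Gsdma, Dst and Insr being the exceptions, and none kept its call in every one, with 65 still called with DESeq2 size factors, 60 with DESeq2, 30 with the length trend removed, 15 with the adipocyte covariate and 0 with the fibroblast covariate. In delta-tocotrienol against control, the edgeR count of 0 (3207 at an unadjusted p under 0.05) became 586 with DESeq2, 2175 with voom quality weights, 2 with 1 surrogate variable (Serinc5, -0.44, and Ptprf, -0.43, chosen after their values were seen) and 0 to 987 with 1 library left out, the highest without control 1; the cause was not tested. In high-fat against delta-tocotrienol, the edgeR count of 0 (393 at an unadjusted p under 0.05) became 6 with DESeq2 and was 0 with voom quality weights and limma-trend.

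Lists called by camera numbered 13, 11 and 12 in these comparisons, 15, 14 and 13 with a replicate block, and 12 to 17, 9 to 14 and 10 to 14 with 1 library left out. With an estimated correlation they were 0, 0 and 3, with fry 2, 0 and 0, and with an estimated correlation without control 2 0, 0 and 0, tests that by construction allow for correlated genes. Direction was kept in every setting by 13 of 13, 10 of 11 and 11 of 12 lists. The exceptions were smooth muscle with delta-tocotrienol (0.06 with 1 surrogate variable) and endothelium in high-fat against delta-tocotrienol (0.05 with the adipocyte covariate). The correlation of the diet responses, 0.819, was 0.858 for genes with a mean log2 CPM of at least 1, 0.313 with the controls split, which removes the shared controls and also leaves 3 in place of 6 in each comparison, and 0.689 without control 2.

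Named genes reversed as follows, in log2 fold change, and the cause was not tested. In high-fat against control, Gsdma had 0.08 with voom quality weights, 0.12 with the surrogate variable, 0.05 with length removed without control 2 and -3.56 to 0.13 with 1 library left out, the highest without control 2; Dst 0.05 and Pten 0.07 with length removed without control 2; Insr 0.01 with length removed and 0.05 also without control 2; Hmgcr -0.06 with library totals, -0.05 and -0.06 with limma-trend, -0.08 with the surrogate variable and -0.1 to 0.11 with 1 library left out, reversing at -0.1, -0.05 and -0.03. Ar had 0.19 with length removed, 0.15 also without control 2, and 0.04, 0 and 0.01 without control 6, high-fat 2 or high-fat 4. In delta-tocotrienol against control, Pten had 0.04 with length removed without control 2, Hmgcr 0 with the block, 0.06 with length removed, 0.11 with the fibroblast covariate and -0.12 to 0.03 with 1 library left out (0.03, 0.03, 0.01, 0.03 and 0.03 where it reversed), and Ar 0.1 with length removed and 0.05 also without control 2. In high-fat against delta-tocotrienol, Pten had 0.02 with voom quality weights, 0.03 with length removed, with and without control 2, 0.05 with the adipocyte and 0 with the fibroblast covariate, and 0 to 0.04 without any of 5 libraries (0.02, 0, 0, 0.04 and 0.01). Hmgcr had -0.02 with library totals, -0.02 and -0.03 with limma-trend and -0.04, -0.01, -0.02 and 0 without any of 4, and Ar -0.01 with the adipocyte covariate and -0.02 to 0.09 with 1 library left out, the lowest without high-fat 5. Library totals moved the median of all genes by -0.07, -0.029 and -0.042 (log2) in these comparisons. Depth was 16256305 to 19235226 counts per library, and some genes had few counts, such as Cd3d at 0.421 CPM with the high-fat diet. Whether depth limited the tests of such genes was not tested.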
